A study of Chlamydomonas reinhardtii with 18 samples.

How the data were processed

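The samples were cells of the green alga *Chlamydomonas reinhardtii*, strain 6145c, kept in the dark at 25 °C. Per the labels' protocols, nitrite was added to 10 mM in 3 treatment flasks, and 3 control flasks received none. Cells of both arms were collected 15 min, 3 h and 24 h later, which gave 18 libraries in 6 groups of 3. Per the design text, the 3 flasks of an arm are its replicates, so the libraries of a group come from separate cultures. The same 6 flasks supply all 3 times.

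Per the labels' protocols, RNA was extracted with a plant NucleoSpin kit and made into stranded TruSeq libraries from the polyadenylated fraction. The submitters' processing notes name TopHat2 2.0.13, a spliced read aligner, and HTSeq, a program that counts reads per gene, with no options. The genome build, the strand setting and the treatment of reads with several alignments are not given in the sources used here. The deposited values are whole-number counts of reads per gene, without normalisation, in 1 table per library. Each table lists 17766 features, of which 17741 are nuclear genes with identifiers ending in the release number 5.5 and 25 are named organelle genes. Each table also ends with 5 summary lines for reads that were assigned to no gene, and these were kept out of library totals and tests. As a share of all reads in a table, reads outside genes made up 0.892% to 1.67%, reads ambiguous between genes 0.0597% to 0.439%, and reads with more than 1 alignment 16.7% to 36.5%. Genes that overlap, or that share sequence with a near-identical copy, can have lost reads to these classes, and their levels are uncertain.

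Totals over genes ran from 6695500 to 8469882 reads per library. Features with too few reads were removed with edgeR's filterByExpr by group (minimum count 10), which left 13564 features and removed 4202. Library sizes were scaled by TMM, and the factors ran from 0.604 to 1.437. CPM values, counts scaled to a common library size, were computed from the deposited counts with these factors. Differences between groups were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F test with robust estimates of the spread. All 18 libraries entered 1 model with a mean per group, which leaves 12 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 13564 features, and a gene is said to have risen, fallen or changed where this value was under 0.05. The standard error (SE) of a log2 fold change was taken as its size over the square root of the F statistic. Values written as mean ± SD are over the 3 libraries of a group. The same model gave 10 comparisons. They are nitrite against control at each of the 3 times, 3 h and 24 h against 15 min within each arm, and the differences between the nitrite effects at each pair of times.

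The tests were tried on simulated counts with 200 changed genes among 13564, besides the 20 light-harvesting loci, which were raised 2-fold. For nitrite against control at 24 h, 89.4% of the genes changed 4-fold, 25.4% of those changed 2-fold and 2.99% of those changed 1.5-fold were recovered, and 1.16% of the calls were false. For the comparison at 15 min the same shares were 93.9%, 41.8% and 7.46%, with 4.72% false, and for 3 h 92.4%, 37.3% and 5.97%, with 4.04% false. For 24 h against 15 min in the control arm they were 81.8%, 34.3% and 2.99%, with 6.67% false. For the difference of the effects at 24 h and 15 min they were 65.2%, 10.4% and 1.49%, with 3.77% false. Most changes of 2-fold or less were thus missed in these simulated counts. Where far more genes change, the adjusted p is less strict. The shares for 24 h therefore do not describe the real comparison, in which 3985 genes (29.4%) were called. All 18 pairs of libraries within groups differed by more than sampling noise, the smallest chi-square per degree of freedom being 4.27, so each library was counted once.

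Of the 17741 nuclear identifiers, 17738 matched a locus tag of the reference gene table of assembly Chlamydomonas_reinhardtii_v5.5, which holds 0 gene symbols and which supplied the coordinates below. Neither the deposited tables nor that table pairs identifiers with names. Genes are therefore printed by identifier, at most 2 that rose and 2 that fell for their size of change per comparison, under the rule fixed before the data were examined. That rule took the largest changes among genes with an adjusted p under 0.05, no overlap between the libraries of both groups and a mean log2 CPM of at least 1, and all tested members of the nitrate and nitrite list and of the nitric oxide list. Functions are given only at the level of lists of loci that were entered from prior knowledge, and the files cannot check this assignment. Other list members named below were chosen after their values were seen.

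There were 28 gene lists fixed before the data were examined, and 7 of them held loci that could be found. They are the lists for nitrate and nitrite uptake and reduction (9 loci, 5 tested), nitric oxide (3, all tested), ammonium and glutamate (7, 6 tested), fermentation (4 entered, 3 tested, and 1 not analysed here), carbon dioxide concentration (7, 4 tested), alternative oxidase (2) and the glyoxylate cycle (2). The other 21 rest on gene symbols and were not analysed here, among them the only list for another cell state, gametes and zygotes. A further 9 lists of loci were added after the identifiers were seen and before any comparison was computed. They are light harvesting (20 loci), Calvin cycle (13), chaperones (14), oxidative stress and glutathione (12), sulfur assimilation (7, 5 tested), photoprotection (5, 1 tested), tubulin (4), mitochondrial mRNA (8, 3 tested) and mitochondrial rRNA (14, 0 tested). The 9 lists with at least 4 tested members were tested with camera of limma 3.58.1 on voom values at a preset correlation of 0.01, adjusted over the lists. Camera asks whether the members of a list moved more one way than other genes did. Calls of single genes were also adjusted over the list alone.

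The alternatives set before the data were examined were no filter and a stricter filter (at least 1 CPM in 3 libraries), size factors by relative log expression and none beyond totals, and DESeq2 1.42.0. They also included voom with the correlation within flasks (-0.057 over all genes), the replicate number or the flask as a block, only the 2 groups compared, a 2-fold threshold, and each library left out in turn. For lists they were an estimated correlation and fry. After the data were seen, fits without the 3 libraries that stand apart were added. Without scaling, the median of all genes moved by -0.46 (log2) for nitrite against control at 24 h, 0.29 at 3 h, -0.29 and -0.71 for 24 h against 15 min in the control and the nitrite arm, and -0.32 for 3 h against 15 min in the control arm. All changes are relative to the TMM-scaled level, in which these medians lie between -0.06 and 0.02. A group with 0 reads was set to 3 reads over the group to bound a fold change, and such bounds and the 95% intervals of ratios cover counting error only. Plots were drawn with matplotlib 3.10.9.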

Results

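The series asked how nitrite acts on the transcripts of *C. reinhardtii*, in a study titled for the biosynthesis of nitrous oxide, a gas that the alga can form from nitrite by way of nitric oxide. Gene expression was measured by sequencing of polyadenylated RNA in 18 libraries. Each arm, control or 10 mM nitrite, had 3 libraries at 15 min, 3 h and 24 h. Time set the libraries furthest apart. The first principal component held 63.3% of the variance and placed the nitrite libraries of 24 h at 116.7 to 120.6 and the control libraries of 24 h at 51.2 to 69, with the 12 earlier libraries between -52.5 and -31.4.

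**Figure D1:**
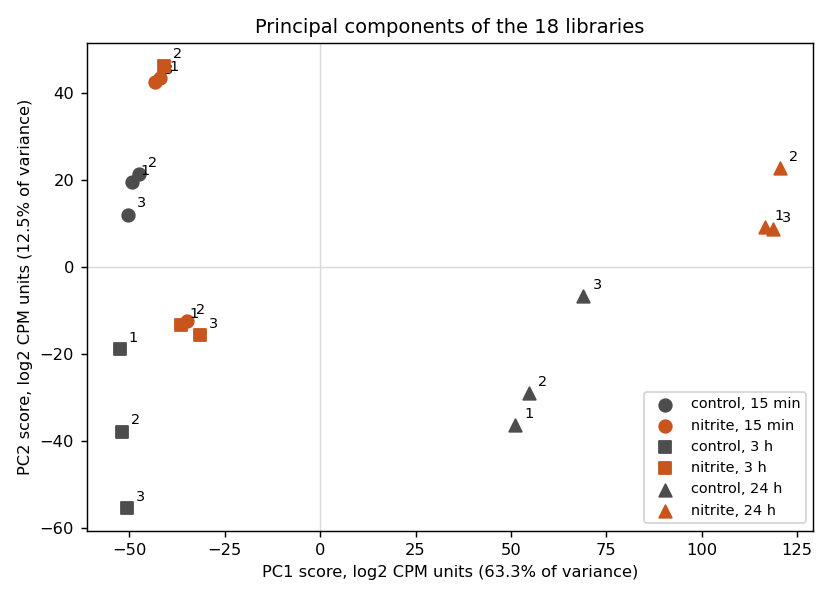
Scores of the 18 libraries on the first and second principal components of log2 CPM over the tested genes, with colour for the arm, symbol for the time and the replicate number beside each point. All 3 nitrite libraries of 24 h lie beyond the 3 control libraries of 24 h on the first component, and the libraries labelled nitrite 15 min number 2 and nitrite 3 h number 2 lie among the libraries of the other time.

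Some libraries stood apart from their groups. The library labelled nitrite 15 min number 2 lay with the nitrite libraries of 3 h, at -12.4 on the second component against 42.5 and 43.4 for the others of its group. The library labelled nitrite 3 h number 2 lay with those of 15 min, at 46.2 against -15.6 and -13.4. In the library labelled control 3 h number 3, reads with more than 1 alignment made up 36.5%, against 16.7% to 21.6% in the other libraries. The mitochondrial mRNAs of that library summed to 874.6 CPM, against 68.38 to 457.4 CPM in the others. All were kept under their labels, and counts without these 3 libraries, a choice made after seeing the data, stand beside each comparison that moved by over 1.5 times.

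At 15 min, 4 genes had risen in the nitrite arm and 0 had fallen. Cre03.g155350 (chromosome 3, 1927266 to 1932452) rose by 1.58 on the log2 scale (SE 0.19, edgeR adjusted p = 0.000512), from 13.1 ± 1.76 to 39.0 ± 7.74 CPM (n = 3 each). Cre04.g215600 (chromosome 4, 1183565 to 1187831) rose by 1.32 (SE 0.21, edgeR adjusted p = 0.0119), from 29.0 ± 5.84 to 72.2 ± 15.6 CPM. Cre03.g155350 was also higher at 3 h, by 1.43, and at 24 h, by 1.70, and Cre04.g215600 by 0.93 and 2.03, all past the test. At 3 h Cre04.g215600 lost its call without nitrite 3 h number 2 (adjusted p = 0.0894) or control 3 h number 2 (0.141). The remaining pair, named because the count is so small and chosen after their values were seen, were Cre12.g517700 and Cre01.g053150. They rose by 1.19 each (SE 0.16 and 0.21, edgeR adjusted p = 0.00228 and 0.0352).

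In the lists closest to the question of nitrous oxide, no member passed the test over all genes at 15 min. The nitric oxide list was entered for a cytochrome P450 of the nitric oxide reductase type and truncated hemoglobins, and 0 of its 3 members passed the test (1 up when adjusted over the list alone). Its most abundant member at this time, Cre01.g007950 (chromosome 1, 1533342 to 1539057), stood at 569 ± 88.7 CPM with nitrite and 532 ± 34.5 CPM without, a log2 fold change of 0.10 (SE 0.23). Cre14.g615400 differed by 0.68, the most in this list, at 131 to 200 CPM with nitrite and 95.5 to 104 CPM without. In the fit without the 3 libraries that stand apart, 1 of the 3 members rose, and 0 of 5 in the nitrate and nitrite list changed. Of the nitrate and nitrite list, entered for reductases and transporters of both ions, 0 of 5 tested members passed, with fold changes from -0.29 to 1.39 on the log2 scale (0 when adjusted over the list alone). The other 4 members had too few reads to test, among them Cre09.g410950 with 3 reads over all libraries. No list passed camera at 15 min, the lowest adjusted p being 0.089. Single members passed when adjusted over the list alone in the carbon dioxide list (1 up), the chaperones (1 down) and the oxidative stress list (1 up).

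The edgeR test left 1101 genes at an unadjusted p under 0.05 for 15 min, while DESeq2 called 28 genes and voom 6. Single libraries moved the count to 2 (without control 15 min number 1 or number 2) or 7 (without nitrite 15 min number 2), and 305 genes were called without the 3 libraries that stand apart, 263 up and 42 down. Cre04.g215600 lost its call without nitrite 15 min number 1 (edgeR adjusted p = 0.0722), control number 1 (0.199) or control number 2 (0.14), and Cre01.g053150 without any library (0.124 to 0.297) but nitrite 15 min number 2. Without scaling none of the 4 passed (adjusted p from 0.216), although Cre03.g155350 and Cre04.g215600 still differed by 1.54 and 1.32 and Cre12.g517700 and Cre01.g053150 by 1.15 and 1.14, nor did they with only the 2 groups compared in the fit (from 0.0576).

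At 3 h, 265 genes had risen and 105 had fallen in the nitrite arm, 2.73% of those tested. Neighbours on chromosome 5 fell furthest. Cre05.g238450 (3012894 to 3018335) stood at 0.919 ± 0.459 CPM with nitrite and 9.18 ± 1.6 CPM without, a log2 fold change of -3.30 (SE 0.45, edgeR adjusted p = 0.00137, n = 3 each). Cre05.g238400 (3008696 to 3012405) changed by -2.98 (SE 0.55, edgeR adjusted p = 0.0176), from 29.5 ± 4.22 to 3.73 ± 0.632 CPM. Both were already lower with nitrite at 15 min, without a call. Cre05.g238450 then had 32 reads against 147 in the control group, and Cre05.g238400 had 104 against 434. Their effects at 3 h and 15 min did not differ past the test (-1.09, edgeR adjusted p = 0.829, and -0.94, 0.858). The largest rises were those of Cre13.g605404 (chromosome 13, 4845472 to 4848143; 6.91 ± 5.25 against 1.11 ± 0.545 CPM) and Cre01.g022950 (chromosome 1, 3573010 to 3576065; 1.43 ± 0.0713 against 0.164 ± 0.147 CPM). Both came to 2.80 on the log2 scale, with SE 0.68 and 0.52. Both went with few reads in the control at 3 h. Unscaled reads of Cre13.g605404 at 15 min, 3 h and 24 h were 118, 20 and 117 in the control groups and 183, 204 and 281 with nitrite. Those of Cre01.g022950 were 25, 4 and 95, and 33, 40 and 218 with nitrite.

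Among the lists, the glyoxylate pair, entered for isocitrate lyase and malate synthase of the pathway that turns acetate into sugar precursors, was higher with nitrite at 3 h. Cre03.g144807 was higher by 0.86 (SE 0.22, edgeR adjusted p = 0.0414), at 167 ± 23.4 CPM with nitrite and 92.0 ± 4.64 CPM without. Its nitrite libraries ran from 153 to 189 CPM at 15 min and from 141 to 186 CPM at 3 h. Its control libraries were lower at 3 h, at 86.7 to 95.4 CPM against 112 to 149 CPM at 15 min. The effects at 3 h and 15 min did not differ past the test for Cre03.g144807 (0.45, edgeR adjusted p = 0.834) or Cre06.g282800 (0.42, 0.858). Cre06.g282800 stood at 992 ± 181 against 562 ± 76.1 CPM, a log2 fold change of 0.82 (SE 0.25, edgeR adjusted p = 0.0728), and 2 of 2 members passed when adjusted over the list alone. In the sulfur assimilation list, Cre10.g445000 rose by 0.75 (SE 0.19, edgeR adjusted p = 0.0377) and 4 tested members did not pass. Of the nitrate and nitrite list 0 of 5 passed, and 1 up and 2 down when adjusted over the list alone. Its member Cre09.g410800 came closest, at -1.64 (edgeR adjusted p = 0.0513). Of the nitric oxide list 0 of 3 passed, by either adjustment, and Cre01.g007950 differed by 0.50 (SE 0.23). The alternative oxidase list had 0 of 2 (1 up when adjusted over the list alone).

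No list passed camera at 3 h, the lowest adjusted p being 0.0781, for tubulin and the Calvin cycle. Tubulin members, which form microtubules, lay between -1.07 and -0.47 on the log2 scale. Without the 3 libraries that stand apart, tubulin (adjusted p = 1.97e-06) and chaperones (adjusted p = 0.0379) passed camera downward, at the preset correlation of 0.01. With all libraries the estimated correlation was 0.405 for tubulin and 0.037 for chaperones, and camera with it gave an adjusted p of 0.348 for each. The correlation was not estimated without the 3 libraries. Of the mitochondrial mRNAs, 0 of 3 passed (3 down when adjusted over the list alone), and the library labelled control 3 h number 3 held the highest level of each with TMM scaling.

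The calls at 3 h rested on single libraries. Without control 3 h number 2 only 7 genes were called, without nitrite 3 h number 2 40, without control number 3 69, without nitrite number 1 212, and without control number 1 1387. Without the 3 libraries that stand apart the count was 232, of which 130 were among the 370. With the replicate number as a block it was 198, 150 up and 48 down. The call of Cre03.g144807 was lost without nitrite 3 h number 2 (edgeR adjusted p = 0.116) or number 3 (0.0752), or control number 2 (0.163) or number 3 (0.0974). That of Cre10.g445000 was lost without nitrite number 1 (0.0847) or number 2 (0.0897), or control number 2 (0.179) or number 3 (0.0867). Cre05.g238400 lost its call without nitrite number 2 (0.0817) or control number 2 (0.0713), Cre01.g022950 without control number 2 (0.0753), and Cre13.g605404 without nitrite number 2 (0.147) or any control library (0.0639 to 0.16). Cre05.g238450 kept its call in all 6 of these fits. With only the 2 groups in the fit 5 genes passed, and Cre03.g144807 and Cre10.g445000 did not (adjusted p = 0.167 and 0.173), nor did they without scaling (0.0586 and 0.0901), where their log2 fold changes were larger, at 1.18 and 1.04. Of the 370 calls, 71.6% were up, and of the 69 made without scaling 66 were (95.7%).

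At 24 h, 2094 genes had risen and 1891 had fallen in the nitrite arm, 29.4% of the genes tested. The largest rise, of Cre04.g217951 (chromosome 4, 674366 to 677377), was 21.6-fold, from 5.48 ± 0.726 to 119 ± 5.41 CPM (log2 fold change 4.44, SE 0.29, edgeR adjusted p = 3.89e-09, n = 3 each). Cre06.g269700 (chromosome 6, 2610966 to 2616181) rose by 4.37 (SE 0.51), from 0.671 ± 0.836 to 13.9 ± 1.07 CPM. Cre08.g358560 (chromosome 8, 270990 to 278300) stood at 0.721 ± 0.206 CPM with nitrite and 16.3 ± 10.8 CPM without, a log2 fold change of -4.46 (SE 0.78, edgeR adjusted p = 0.000489). Cre17.g742250 (chromosome 17, 6238708 to 6243214) had 0 reads in the nitrite libraries of 24 h and 20 in the control libraries, which makes it at least 5.15-fold lower, and it lost its call with any library left out (edgeR adjusted p 0.0579 to 0.119).

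Both loci of the glyoxylate list rose at 24 h. Cre06.g282800 (chromosome 6, 5284370 to 5288359) rose 2.83-fold, from 1290 ± 531 to 3660 ± 179 CPM (log2 fold change 1.5, SE 0.26, edgeR adjusted p = 0.000167). Cre03.g144807 (chromosome 3, 356536 to 361981) rose 2.69-fold, from 312 ± 130 to 839 ± 27.3 CPM (1.43, SE 0.23, edgeR adjusted p = 7.74e-05). Of the alternative oxidase list, whose enzymes pass electrons from ubiquinol to oxygen in the mitochondrion, Cre03.g169550 rose 3.22-fold, from 1.01 ± 0.455 to 3.26 ± 0.715 CPM. Its log2 fold change was 1.69 (SE 0.43, edgeR adjusted p = 0.00574), which became 1.29 (adjusted p = 0.0537) without scaling. The other member, Cre09.g395950, stood at 129 ± 13.7 against 91.3 ± 12.9 CPM and did not pass (0.50, SE 0.32). Without the 3 libraries that stand apart, 2 of 2 members rose.

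**Figure D2:**
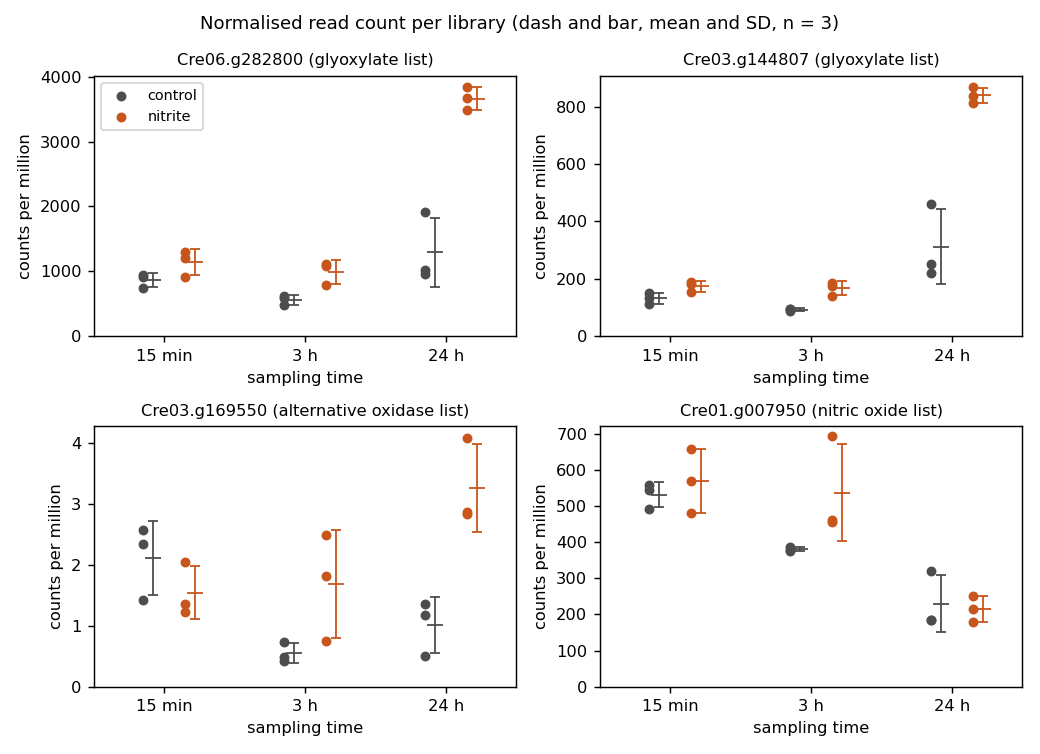
Normalised read count in CPM (vertical axes, linear and starting at 0) at each sampling time (horizontal axes) for 4 list loci, with a point per library and a dash and bar for mean and SD, n = 3, grey for control and orange for nitrite. At 24 h the nitrite libraries of Cre06.g282800 averaged 3660 against 1290 CPM, while those of Cre01.g007950 averaged 215 against 230 CPM.

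The stress lists moved both ways at 24 h. Of the oxidative stress and glutathione list, entered for enzymes that remove peroxides and superoxide, 4 of 12 members rose, 1 fell and 7 did not pass. Cre10.g456750 rose by 1.46 (SE 0.22) and Cre09.g417150 by 0.94 (SE 0.25). Without scaling the calls of Cre09.g417150 (0.53, adjusted p = 0.231), Cre16.g688550 (0.41, 0.323) and Cre10.g458450 (0.29, 0.535) ended, which left that of Cre10.g456750 among the 4 rises. Of the chaperone list, proteins that assist folding, 2 of 14 rose, 2 fell and 10 did not pass. Cre03.g145787 rose 4.19-fold, from 48.1 ± 16.8 to 202 ± 9.51 CPM (2.07, SE 0.27), and Cre17.g741450 changed by -1.35 (SE 0.32). The other rise, of Cre02.g090850, ended without scaling (0.01, adjusted p = 0.981). Of the sulfur assimilation list, 2 of 5 rose and 1 fell. Both rises ended without scaling, those of Cre12.g502600 (1.19, adjusted p = 0.0802) and Cre10.g445000 (0.15, 0.751). Adjusted over the list alone, the counts of these lists were the same. Cre10.g456750, Cre09.g417150, Cre03.g145787 and Cre17.g741450 kept their calls with any 1 library left out, and the other called members of these 3 lists each lost theirs without at least 1 library (adjusted p up to 0.195).

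Few members of the carbon and nitrogen lists passed the test at 24 h. In the Calvin cycle list 1 of 13 rose, Cre08.g380250 by 1.18 (SE 0.24), and in the ammonium and glutamate list 1 of 6 fell, Cre02.g113200 by -0.71 (SE 0.18). Of the light-harvesting list 0 of 20 passed (median 0.12), and the fermentation (0 of 3), carbon dioxide (0 of 4), tubulin (0 of 4), photoprotection (0 of 1) and mitochondrial mRNA (0 of 3) lists held no call, also when adjusted over the list alone. Of the nitrate and nitrite list 0 of 5 passed by either adjustment, and its median was -0.93, or -0.04 with the 2 members at 0 reads in the nitrite libraries set to their bound. Of the nitric oxide list 0 of 3 passed (1 up and 1 down when adjusted over the list alone). Without the 3 libraries that stand apart, where 5211 genes were called rather than 3985, some of these lists gained calls. The nitrate and nitrite list then had 2 down, the nitric oxide list 1 up and 1 down, and ammonium and glutamate 1 up and 2 down. Fermentation had 1 up and light harvesting 2 up. Cre01.g007950 stood at 215 ± 36.2 against 230 ± 79.1 CPM (-0.10, SE 0.23), Cre14.g615400 at 184 ± 30.8 against 132 ± 14.6 (0.48, SE 0.19, edgeR adjusted p = 0.0565) and Cre14.g615350 at 4.30 ± 0.934 against 12.8 ± 7.24 (-1.58, SE 0.66).

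No list passed camera at 24 h, the lowest adjusted p being 0.828. Fry, which does not compare a list with other genes, asks whether members move on balance 1 way. It called sulfur assimilation (fry adjusted p = 0.044), the list whose rises ended without scaling. Its test for moves in either direction gave an adjusted p of 0.000251 for chaperones, 0.000833 for oxidative stress and 0.204 or more for the other lists. That test too sets no list against other genes, of which 29.4% of all tested changed at 24 h. Of the genes changed, 2233 changed at least 2-fold. The split of 52.5% up became 17.1% of the calls made without scaling and 55.0% with relative log expression factors.

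**Figure D3:**
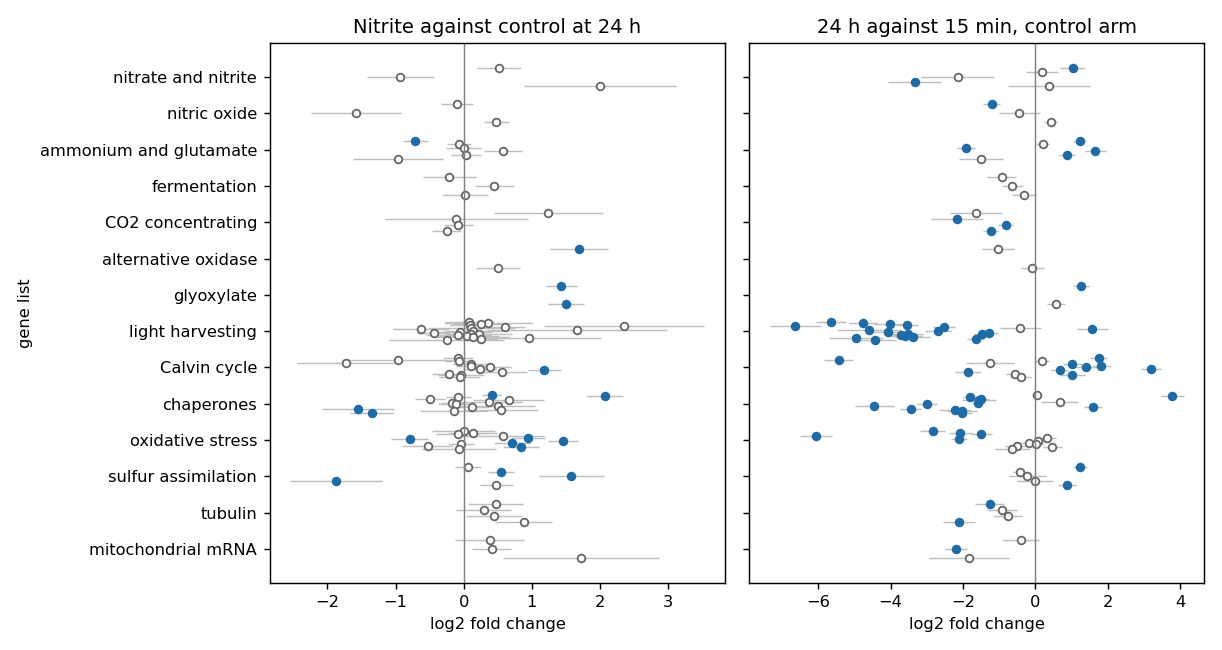
Log2 fold changes of the tested members of 14 gene lists (a point per locus, horizontal bar 1 SE) for nitrite against control at 24 h and for 24 h against 15 min in the control arm, filled where the edgeR adjusted p was under 0.05. Loci with 0 reads in a whole group are left out, and the light-harvesting list holds 0 calls of 20 in the first panel and 19 in the second.

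The genes called at 3 h and at 24 h overlapped. Of the 265 that rose at 3 h, 193 had also risen at 24 h (40.9 expected of independent lists), and of the 105 that fell 52 had also fallen (14.6 expected). Genes called in opposite directions numbered 8 (53.2 expected). The neighbours Cre05.g238450 and Cre05.g238400 were among these 8, higher with nitrite at 24 h by 1.26 (SE 0.37) and 2.54 (SE 0.54). Cre05.g238400 stood at 28.1 ± 27.3 CPM with nitrite and 4.79 ± 1.25 without, and its fold change was 1.41 (adjusted p = 0.00723) without nitrite 24 h number 1. At 24 h Cre05.g238450 lost its call without nitrite 24 h number 1 (adjusted p = 0.174), control 24 h number 1 (0.0687) or scaling (0.177), and with only the 2 groups in the fit it (0.0735) and Cre05.g238400 (0.086) did not pass.

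The test of the difference itself found 936 genes whose nitrite effect at 24 h differed from that at 15 min, 435 toward higher and 501 toward lower values. For Cre04.g217951 the effects differed by 3.99 (SE 0.43) and for Cre05.g238400 by 4.58 (SE 0.77), while Cre08.g358560 differed by -4.49 (SE 0.95). Of the list members named above, Cre03.g169550 (2.09, SE 0.59), Cre03.g145787 (1.87, SE 0.44), Cre10.g456750 (1.32, SE 0.32) and Cre08.g380250 (1.26, SE 0.34) had a larger effect at 24 h. For the glyoxylate loci, Cre06.g282800 and Cre03.g144807, the differences were 1.1 (edgeR adjusted p = 0.0623) and 1.01 (0.054), which did not pass over all genes but did when adjusted over the list alone (2 of 2). Without scaling the differences of the 4 list members with a larger effect did not pass (adjusted p 0.0759 to 0.285). Cre03.g169550 lost its call in 8 of the fits without 1 library (0.0533 to 0.115), with the flask (0.0669) or the number (0.0548) as a block and by voom (0.052), Cre08.g380250 in 7 (0.0542 to 0.0928) and Cre03.g145787 without control 15 min number 2 (0.0554), and Cre08.g358560 by voom (0.114). The share toward higher values was 46.5%, or 13.8% of the 334 calls made without scaling. The count was 422 without control 24 h number 1, 474 without its number 2, 508 without control 15 min number 2, 539 without nitrite 24 h number 2, 622 without its number 3, and 1763 without the 3 libraries that stand apart.

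Between 24 h and 3 h the effects differed for 750 genes, 415 toward higher and 335 toward lower values. Cre05.g238400 and Cre05.g238450 differed most, by 5.52 (SE 0.77) and 4.56 (SE 0.59), and Cre03.g145787 by 1.87 (SE 0.43), Cre10.g456750 by 1.37 (SE 0.32) and Cre08.g380250 by 1.46 (SE 0.34). The calls of these 3 ended without scaling (adjusted p 0.0983, 0.313 and 0.12). Those of Cre03.g145787 (0.0778) and Cre10.g456750 (0.0509) also ended without control 3 h number 2, that of Cre10.g456750 without nitrite 24 h number 1 (0.0514), and that of Cre08.g380250 without control 24 h number 2 (0.053). One mitochondrial mRNA of 3 also differed (3 when adjusted over the list alone), with the library labelled control 3 h number 3 holding the highest level of each with TMM scaling. The share toward higher values was 55.3%, or 3.71% of the 1131 calls made without scaling. The count was 393 and 406 without control 24 h number 2 and number 1, 445 without nitrite 24 h number 1, 471 and 1160 without control 3 h number 2 and number 1, and 1337 without the 3 libraries that stand apart. Between 3 h and 15 min, edgeR called 0 genes (814 at an unadjusted p under 0.05; DESeq2 3, voom 0), and 12 without the 3 libraries that stand apart.

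In the dark without nitrite, light-harvesting transcripts, which encode the proteins that bind chlorophyll in the antennae, fell between 15 min and 24 h. Of 20 members 18 fell and 1 rose, with a median of -3.58 on the log2 scale. Cre01.g066917 went from 1120 ± 101 to 22.6 ± 6.19 CPM (-5.64, SE 0.41) and Cre06.g278213 from 14.3 ± 1.73 to 0.129 ± 0.131 CPM (-6.63, SE 0.71), while Cre06.g284200 rose by 1.57 (SE 0.43). Camera gave an adjusted p of 2.03e-11 for the list, and adjusted p = 0.132 with an estimated correlation. Most chaperones fell as well, 10 of 14, while 2 rose (adjusted p = 0.00161, and 0.0539 with an estimated correlation). Their extremes were Cre09.g386750 at -4.45 (SE 0.53) and Cre03.g145787, which rose by 3.78 (SE 0.32). Of the oxidative stress list 5 of 12 fell (adjusted p = 0.0279, and 0.356 with an estimated correlation), Cre06.g257601 by the most, at -6.06 (SE 0.45).

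Other lists split in the control arm. In the Calvin cycle list, entered for carbon fixation, 7 of 13 rose and 2 fell (7 and 3 when adjusted over the list alone). Cre05.g234550 went from 4110 ± 79.9 to 37800 ± 2050 CPM (3.20, SE 0.27) and Cre01.g029300 from 25.1 ± 2.48 to 0.561 ± 0.326 CPM (-5.44, SE 0.40). In the ammonium and glutamate list 3 of 6 rose and 1 fell (3 and 2 over the list alone), Cre12.g530600 by 1.66 (SE 0.29) and Cre12.g514050 by -1.92 (SE 0.24). The carbon dioxide list had 3 of 4 down (4 over the list alone), tubulin 2 of 4, photoprotection 1 of 1, and sulfur assimilation 2 of 5 up. In the nitrate and nitrite list 1 of 5 rose and 1 fell. Of the nitric oxide list, Cre01.g007950 fell by 1.21 (log2, SE 0.23), from 532 ± 34.5 to 230 ± 79.1 CPM, and the others did not pass. Of the glyoxylate list Cre03.g144807 rose by 1.25 (SE 0.22), and 2 of 2 passed over the list alone. No member of the fermentation or alternative oxidase list passed. Of the 3 tested mitochondrial mRNAs only nad4, for a subunit of respiratory complex I, passed, at -2.20 (SE 0.30). How many such reads came from outside the polyadenylated fraction was not tested for this comparison.

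In all, 2816 genes rose and 3000 fell from 15 min to 24 h in the control arm, 42.9% of those tested, 3541 of them at least 2-fold. Cre06.g292315 (chromosome 6, 6412147 to 6413598) rose most, from 0.799 ± 0.304 to 71.1 ± 20 CPM (6.50, SE 0.39), followed by Cre03.g197850 (5.53, SE 0.50). Cre24.g755997, on an unplaced scaffold, went from 216 ± 16.3 to 0.255 ± 0.221 CPM (-9.61, SE 1.27), and Cre13.g577352 was at least 43.5-fold lower, with 0 reads at 24 h. The share of rises was 48.4%, or 26.7% of the calls made without scaling.

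Light-harvesting transcripts also fell in the nitrite arm, 19 of 20 from 15 min to 24 h, with a median of -3.24 (camera adjusted p = 1.23e-07, and adjusted p = 0.266 with an estimated correlation). Both glyoxylate loci rose, Cre03.g144807 by 2.26 (SE 0.23) and Cre06.g282800 by 1.68 (SE 0.26). Of the chaperones 9 of 14 fell and 3 rose (adjusted p = 0.0856), Cre03.g145787 going from 4.03 ± 1.31 to 202 ± 9.51 CPM (5.65, SE 0.34). Of the Calvin cycle list 6 of 13 rose and 4 fell, of oxidative stress 2 of 12 rose and 6 fell (3 and 7 when adjusted over the list alone), of ammonium and glutamate 3 of 6 rose and 2 fell, and of sulfur assimilation 3 of 5 rose. The carbon dioxide list had 3 of 4 down, fermentation 1 of 3 down and alternative oxidase 1 of 2 up, and tubulin had no call. Of the nitric oxide list 2 of 3 fell, Cre01.g007950 by 1.41 (log2, SE 0.23), from 569 ± 88.7 to 215 ± 36.2 CPM. In the nitrate and nitrite list 1 of 5 rose and 2 fell (1 and 3 over the list alone), both to 0 reads at 24 h, as did the tested photoprotection locus. Of the 3 tested mitochondrial mRNAs only nad4 passed, at -1.43 (SE 0.30), and reads from outside the polyadenylated fraction were not tested here either.

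From 15 min to 24 h in the nitrite arm 3763 genes rose and 4206 fell, 58.8% of those tested. Cre06.g269700, with 0 reads at 15 min, was at least 130-fold higher, and Cre06.g254300 (chromosome 6, 824863 to 826768) rose by 8.10 (SE 0.46). Cre24.g755997 fell, the ratio of 15 min to 24 h being 1550 (95% interval 429 to 12800), with 2 reads at 24 h. Cre03.g162500 (chromosome 3, 2843685 to 2847020) was at least 47.8-fold lower. The share of rises was 47.2%, or 18.8% of the calls made without scaling.

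Between 15 min and 3 h the light-harvesting list moved down in the control arm by camera (adjusted p = 1.35e-05), and adjusted p = 0.595 with an estimated correlation. No single member passed over all genes, and 11 down and 2 up passed when adjusted over the list alone. Cre06.g267600 (chromosome 6, 2357352 to 2364003) rose most, by 3.01 (SE 0.64), from 1.11 ± 0.0924 to 8.87 ± 1.19 CPM, and Cre11.g467532 (chromosome 11, 86916 to 89667) fell most, at -2.10 (SE 0.51), or -3.76 without control 3 h number 1. One Calvin cycle locus of 13 was the only call in a list. In all, 118 genes rose and 53 fell. That count was 3 to 15 with any library but control 3 h number 1 left out (control 15 min number 1 6, number 2 4 and number 3 4; control 3 h number 2 3 and number 3 15), and both named genes then lost their calls, as they did without scaling (adjusted p = 0.0951 each). With arm and number taken as the flask and used as a block, although the labels do not say that a number marks a flask, 4 genes were called, and Cre06.g267600 (0.114) and Cre11.g467532 (0.121) were not among them. It was 894 without control 3 h number 1 and 1645 without the 3 libraries that stand apart, with light harvesting at 15 of 20 down and 1 up.

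In the nitrite arm edgeR called 0 genes between 15 min and 3 h (197 at an unadjusted p under 0.05; DESeq2 0, voom 0), while 3 lists moved down by camera. These were light harvesting (adjusted p = 1.59e-07, and adjusted p = 0.379 with an estimated correlation), tubulin (0.00925, and 0.4) and oxidative stress (0.038, and 0.48). The libraries labelled nitrite 15 min number 2 and nitrite 3 h number 2 belong to this comparison. Without these and control 3 h number 3, 2865 genes were called, 1404 up and 1461 down, with light harvesting at 17 of 20 down and 2 up, tubulin at 3 of 4 down and oxidative stress at 5 of 12 down.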

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

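The tests of exchanged labels, of a different flask and of transcripts outside the polyadenylated fraction were chosen only after the patterns were seen, as were the fits without libraries that stand apart, the repeated thinning, the trends with gene span between pairs of libraries, the mitochondrial levels without scaling and the share expected from the shares of rises. The number of draws for the differences was changed, and set at 100, after results from fewer draws had been seen. Groups of 3 libraries were not tested for libraries far from the others.

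A test of the difference itself picked out the genes whose nitrite effect was not the same at 24 h as earlier. Against 15 min there were 936. Cre05.g238400 (4.58), Cre04.g217951 (3.99) and Cre05.g238450 (3.47) had higher values at 24 h and Cre08.g358560 (-4.49) and Cre07.g325755 (-4.31) lower ones. Cre07.g325755 had 1 read in the nitrite libraries of 24 h, and without number 2 of these its difference was -6.53. Of the list members, the alternative oxidase locus Cre03.g169550 differed by 2.09, the chaperone locus Cre03.g145787 by 1.87, the oxidative stress locus Cre10.g456750 by 1.32 and the Calvin cycle locus Cre08.g380250 by 1.26. Cre03.g169550 lost its call with the flask (edgeR adjusted p = 0.0669) or the number (0.0548) as a block, by voom (0.052) and in 8 of the fits without 1 library (0.0533 to 0.115), and all 4 lost theirs without scaling (0.0759 to 0.285). Of 100 draws that assigned the libraries of each time to the arms anew, the real one included, 11 gave at least 936 genes, the highest other 2832, so chance was not excluded by this share. Those counts point to a structure of the samples: all 11 kept the arms of 24 h whole and so still held the effect of 24 h, and the highest of the 89 draws that mixed them was 0.

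Against 3 h, 750 genes differed, among them Cre05.g238400 (5.52), Cre05.g238450 (4.56), Cre04.g217951 (4.15), Cre03.g145787 (1.87), Cre08.g380250 (1.46), Cre10.g456750 (1.37) and Cre04.g215600 (1.1). Lower at 24 h were Cre07.g327650 (-4.23, 2 reads in the nitrite libraries of 24 h) and Cre08.g358560 (-4.18). Cre08.g358560 lost its call without nitrite 24 h number 1 (edgeR adjusted p = 0.0617) or number 2 (0.0516), without the 3 libraries that stand apart (0.0659) and by voom (0.171). Cre07.g327650 lost it in 8 of the fits without 1 library (0.0537 to 0.0891), with the flask as a block (0.0673) and by voom (0.146). Cre04.g215600 lost it in 8 of the fits without 1 library (0.051 to 0.0845), and without scaling its difference was 0.29 (0.573). Of 100 draws 12 gave at least 750 genes, the highest other 2778, so chance was not excluded by this share. All 12 kept the arms of 24 h whole, and the highest of the 87 that mixed them was 43. Between 3 h and 15 min all 100 draws gave at least the real count of 0 (edgeR; 814 at an unadjusted p under 0.05, DESeq2 3, voom 0), the highest other 798, in a draw that kept the arms of 3 h whole.

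In the summary lines, which no comparison uses, 3 classes of reads assigned to no gene were compared at 3 times. Reads ambiguous between genes made up 0.337% (SD 0.086) with nitrite and 0.144% (SD 0.028) without at 15 min, and 0.371% (SD 0.093) and 0.161% (SD 0.04) at 24 h. Reads with more than 1 alignment made up 21.1% (SD 0.84) and 18.1% (SD 1.2) at 24 h. The exact permutation p was 0.1 for each of these 3, the smallest that 3 against 3 libraries can give, and 0.2 to 0.8 for the other 6. Reads with more than 1 alignment made up 19.3% with nitrite and 24.7% without at 3 h (exact permutation p = 0.7), where control number 3 held 36.5% and the other controls 18.1% and 19.4%. No biological explanation was tested.

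The libraries labelled nitrite 15 min number 2 and nitrite 3 h number 2 lay with the other time. Their distances to the libraries of their own label were 1.96 and 1.88 times those to the other time, against 0.911 to 0.943 for the other 4 nitrite libraries of these times. Exchanged labels stay open: the smaller ratio, 1.88, is what an exchange needs. A flask that differs from the other 2 in the same way at both times is argued against. On the second component number 2 lay at -12.4 against 42.5 and 43.4 at 15 min. At 3 h it lay at 46.2 against -15.6 and -13.4, the opposite shift. The deviations of the 2 libraries correlated at -0.77 across genes, but this restates that each lies with the other time. Numbers 1 and 3 of these groups gave -0.47 and -0.39. A flask whose difference changed between these times stays open, and the labels do not say that a number marks a flask. The labels were kept, and a difference between the cultures at these times was not tested.

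The library labelled control 3 h number 3 stood apart from its group, at a distance ratio of 1.45 at full depth. After the 3 libraries of its group were thinned to its total, the ratio was 1.41 (1.4 to 1.42 in 20 thinnings). This argues against the total of reads as the whole cause, expected at 1.2 or less. Thinning made only the totals equal. The TMM factor of 0.604, against 1.323 and 0.892 for numbers 1 and 2, still left number 3 with a lower effective depth, which was not tested. The bound set beforehand against depth lay above the ratio at full depth and could not be met. Fewer reads from long genes stay open: its deviations fell with gene span (Spearman -0.44, against -0.24 to 0.5 in the other 17 libraries), but the 0.5 is that of number 1 of its own group, and number 1 less number 2 gave 0.39 where number 3 less number 2 gave -0.32, so the trend cannot be assigned to number 3 alone. More reads from outside the polyadenylated fraction stay open too: for 3 of 3 tested mitochondrial mRNAs it held the highest level of all libraries with TMM scaling (its factor 0.604), but for 2 of 3 without scaling (nad4 at 326 against 339 CPM), and their summed level had been seen before the test. No biological explanation was tested.

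At 24 h, 2983 of the 3985 genes changed by nitrite (74.9%) moved in the direction in which the control arm moved from 15 min to 24 h. Of 2050 that were also called in the control arm, 1740 did (84.9%). The other 1935 had no call there, so their direction in the control arm rests on uncalled estimates. The 24 h control libraries that the nitrite change and the control change share would make their covariance across genes negative. It was 0.252 (correlation 0.32), against -0.048 (SD 0.0031, correlation -0.14) in simulated counts. The positive value argues against the shared libraries alone. The simulated genes varied independently, so the SD leaves out variation that genes share between cultures. How far 0.252 lies from a chance difference between cultures was not tested. Gene length is argued against too, with at least 74.1% in each of 3 classes of gene span. For scaling the share cannot decide: without it 77.1% moved the same way, but the shares of rises alone then give 62.4% (50.3% with TMM), above the bound set beforehand. A scaling factor moves the log2 changes of all genes by about the same amount, which leaves their covariance across genes as it is. The 0.252 thus argues against scaling as the whole cause. That nitrite hastens or deepens the change of the dark culture is a hypothesis that the 0.252 leaves open, found and tested on the same libraries.

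The 10 splits of 3 against 3 libraries are too few for a share under 0.05. For nitrite against control the real split was the 1 with the most calls at 15 min (4, highest other 0), 3 h (370, 0) and 24 h (3985, 0). So it was within the control arm at 3 h (171, highest other 14) and 24 h (5816, 0), and within the nitrite arm at 24 h (7969, 0). For 3 h against 15 min in the nitrite arm all 10 splits gave at least the real count of 0, and the highest other gave 4393. That split put each library labelled number 2 with the other time, which points to a structure of the samples. For lists passing camera, nitrite against control gave 0 at each time, with highest others of 4, 3 and 1, and 10 of 10 splits as many. In the control arm 6 of 10 splits gave at least the real 1 at 3 h (highest other 2) and 3 of 10 the real 3 at 24 h (4). In the nitrite arm 5 of 10 gave at least the real 3 at 3 h (4) and 9 of 10 the real 1 at 24 h (3).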

How the results depend on the processing

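The fits without the 2 or 3 libraries that stand apart, for genes and lists, were chosen after seeing the data. Named genes with a call kept their direction in all 1467 combinations of gene, comparison and alternative and their call in 1268. In 50 of 89 gene and comparison pairs no alternative ended it. Of 410 for genes without a call, 361 stayed as they were, 32 gained a call and 17 turned.

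Counts of genes moved as follows, and the causes were not tested beyond what each setting takes away. No scaling gave 0 at 15 min and 69 at 3 h for nitrite, 0 for 3 h in the control arm, and 334 and 1131 for the differences of 24 h from 15 min and 3 h. The number as a block gave 198 at 3 h and 14 for 3 h in the control arm, the flask as a block 4 and voom 69 for the latter. A 2-fold threshold left 188 at 3 h, 2233 at 24 h and 3541 for 24 h in the control arm. Only the groups compared gave 0 at 15 min, 5 at 3 h and 1271 for 3 h in the control arm. DESeq2 gave 28, 933, 667 for the same and 3 for the difference of 3 h and 15 min. Without the 2 nitrite libraries, 15 min gave 230, 3 h in the control arm 1980, in the nitrite arm 2446, and the differences of 3 h from 15 min and 24 h from 3 h 7 and 1338. Without the 3, these were 305, 1645, 2865, 12 and 1337, with 232 at 3 h and 1763 for 24 h from 15 min.

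With each library left out, nitrite gave 2 to 7 genes at 15 min, 7 to 1387 at 3 h and 2852 to 3866 at 24 h. The control arm gave 3 to 894 at 3 h and 4892 to 5074 at 24 h, the nitrite arm 0 to 0 and 7147 to 7871. The differences gave 0 to 4 (3 h from 15 min), 422 to 1328 (24 h from 15 min) and 393 to 1160 (24 h from 3 h).

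Lists passing camera numbered 2 at 3 h without the 3 libraries, and fry called 1 at 24 h in its test of moves 1 way, which the counts of fry here refer to. Within arms the estimated correlation left 0 in all 4 comparisons, fry 8 and 6 at 24 h in the control and nitrite arm and 0 at 3 h in the nitrite arm, and the fit without the 3 libraries 5 at 24 h in the control arm.

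Values that turned were all without a call. With 1 library left out, Cre03.g177700 at 15 min ran from -0.13 to 0.25 (among them -0.02), Cre02.g110800 at 3 h from -0.36 to 0.46 (among them 0.19), Cre14.g615350 at 15 min from -0.78 to 0.6, Cre09.g410900 at 15 min from -1.53 to 1.6, and Cre01.g007950 from -0.02 to 0.21 at 15 min and from -0.24 to 0.22 at 24 h (among them 0.05). Without scaling the first 2 gave -0.04 and 0.19 and Cre14.g615400 at 3 h 0.24, and voom gave -0.14 for Cre14.g615350. Without the 3 libraries these were -0.02 (Cre03.g177700), 0.02 (Cre14.g615400), -0.81 (Cre14.g615350) and -1.55 (Cre09.g410900).

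The numbers were not taken to pair the samples, since the labels do not say that a number marks a flask. Of 45 pairs of libraries with the same number 8 correlated above 0.1 (-0.77 to 0.38), among them control 15 min and 3 h for number 1 (0.38) and number 3 (0.37), and 6 of 18 libraries correlated best with their own number. In simulated counts with 200 changed genes, far fewer than the 3985 called for nitrite at 24 h, most changes of 2-fold or less were missed.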

Other observations

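The value for neighbours under 1 kb apart was chosen after the result for other pairs was seen.

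Coordinates allow a hypothesis outside the comparisons, that neighbouring genes respond to nitrite together at 24 h, as the chromosome 5 neighbours Cre05.g238400 and Cre05.g238450 did. Of 3845 adjacent tested pairs at least 1 kb apart, 4.27% changed in the same direction, within the 3.3% to 5.31% of 1000 shuffles, so these pairs showed no excess. Of 9589 pairs under 1 kb apart it was 6.38%, above the 3.75% to 4.96% of shuffles, and reads shared between overlapping ends of such close genes were not separated from shared control.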
